A study of Homo sapiens with 6 samples.

How the data were processed

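RNA was measured in 6 libraries of the human natural killer cell line NK-92, 3 from cells transfected with an empty vector and grown for 2 days with recombinant human IL2, and 3 from cells transfected with a vector for a membrane-bound IL2 (mbIL2) and grown for 2 days without it. Per the labels' protocols, RNA was taken up in Trizol and libraries were made from total RNA with a TruSeq RNA kit, whose catalogue entry in the labels does not say whether strand was kept. Groups and replicate numbers were taken from the sample titles and treatments. The design text of the series calls the cultures of each group biological replicates, each cultured and collected separately. It does not say how many transfected populations they came from.

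The authors deposited a single matrix of TPM (transcripts per 1000000 transcripts) with 59194 listed genes and 1 column per library. Bowtie2 2.4.1, RSEM 1.3.3 and the genome build GRCh38 are named, without their roles, in the submitters' processing notes. The annotation, any trimming and any filter on reads were not given in the sources used here. Each column summed to 1000000 within rounding. TPM keeps no depth, so the number of reads behind each value is unknown, and no counting interval or detection limit was computed. A value of 0 is reported only as listed at 0. TPM also sets every library to the same total, so a change in the make-up of a library moves all its other genes.

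Symbols came from a gene name table, which matched 58472 of the 59194 identifiers. Another 310 entries were assembled loci with no gene identifier, of which 272 were tested. Positions, gene types and exonic overlaps came from GENCODE release 29 on GRCh38, and transcript length and GC content from its longest transcript per gene. Of the 145 genes that the naming rule took, 43 share at least 50 exonic bases with another gene, and for these, as for members of near-identical families (granzymes, S100 genes, histones, ribosomal proteins, XCL and CCL chemokines, killer receptors), the values could hold reads of the other gene.

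Genes with a mean of at least 1 TPM over the 6 libraries were tested, 13738 in all. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 1), 2-sided, with group as the only term and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. A further count required an absolute log2 fold change of at least 1. Every fold change is on the log2(TPM + 1) scale, mbIL2 minus vector, and understates changes of low genes. Values after ± are SD over n = 3 libraries unless a standard error (SE) is named. Because the median of all genes moved on this scale, each fold change was also computed after the columns were rescaled by the median of ratios, taken over genes above 0 in all 6 libraries, and is called rescaled below.

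The 31 gene lists were fixed before the data were examined, as were the groups, the main tests, the named genes rule and the alternative settings. Lists were tested with camera in limma at its preset correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the 29 lists that had them. Camera with the correlation estimated for each list and fry, which tests whether a list's own genes move one way on balance, were alternatives. Named genes were 25 fixed genes of the IL2 pathway and of natural killer function, the 10 largest log2 fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 TPM and no overlap between the groups, and up to 2 list members per direction with the smallest adjusted p. Clone names, small RNAs, pseudogenes, mitochondrial rRNA and genes of sex chromosome dosage were left out of the largest changes. Where a list had a passing member, the text gives some of those members.

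Values per library were compared with a 2-sided exact permutation test of the difference of means, whose smallest possible p with 3 against 3 libraries is 0.1. Along the chromosomes, the median log2 fold change of protein-coding genes was taken in 20 Mb windows with at least 30 genes, relative to the median of all such genes, and set against 1000 permutations of the genes over positions. Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, limma without trend and with robust estimation, the replicate number as a block, and each library left out in turn. A fit without the genes of 7 shifted windows was added after the data were seen.

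The script was tested on simulated data in which 200 of 13738 genes were changed, in 5 simulations of the mbIL2 against vector comparison. It recovered 69.4% of genes changed by a log2 fold change of 1 and 92.6% of those changed by 2, with 6.68% of calls false. The simulated genes varied independently and rose as often as they fell, with no shift of the median and no library set apart. These rates need not hold for the real calls. A shifted list was called in 5 of 5 simulations, and 0 of 250 unshifted lists were called. Those lists were drawn without the correlation between genes that real lists have. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.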

Results

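NK-92 is a human natural killer lymphoma line that needs IL2 to grow. The comparison asks how the transcriptome of NK-92 cells that carry their own membrane-bound IL2 (mbIL2) and were kept without recombinant IL2 differs from that of empty-vector cells kept with recombinant human IL2. It covers 3 libraries of each kind, all at day 2. Vector and IL2 source changed together, so they form a single contrast. The p-values of the gene tests measure the spread between separately grown cultures. The number of transfected populations is not given, so a difference between populations cannot be told apart from an effect of mbIL2. The read depth of the libraries is unknown, since TPM does not keep it.

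The groups stood apart. Correlations of log2(TPM + 1) across the 13738 tested genes ran from 0.941 to 0.948 between the groups, from 0.970 to 0.982 among vector libraries and from 0.975 to 0.976 among mbIL2 libraries. The first principal component held 56.7% of the variance and separated the groups. The next held 15.4% and set vector replicate 3, at -40.2, apart from vector replicates 1 and 2, at 17.5 and 14.6. The values of the groups did not overlap in 55.8% of genes, where chance gives 10%. In mbIL2 libraries, 13983 ± 74 genes reached 1 TPM, against 13181 ± 249 in vector libraries, and the 50 most abundant genes took 22.2% ± 0.236 of the total against 24.1% ± 0.830 (exact permutation p = 0.1 for each, the smallest this design allows). Mitochondrial transcripts took 5.41% ± 0.307 against 5.97% ± 0.456 (exact permutation p = 0.3).

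In mbIL2 cells 4533 genes were higher and 1338 lower, and 617 and 269 of these changed by an absolute log2 fold change of at least 1. The median of all tested genes was itself 0.23 higher in mbIL2 cells. After rescaling it was 0.00, with 1890 genes higher and 2487 lower, so the share of calls that were higher went from 77.2% to 43.2%. All 1890 of those higher genes and all 1338 of the lower genes were called in the same direction on both scales. The number of genes higher in mbIL2 was 2990 without mbIL2 replicate 2 and 2953 without mbIL2 replicate 3.

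IL2 itself was listed at 0 TPM in vector replicates 1, 2 and 3, and at 21.5, 24.5 and 24.2 TPM in mbIL2 replicates 1, 2 and 3 (adjusted p = 7.6e-06). The gene lies on chromosome 4 at 122451470 to 122456725 of GRCh38. The sequence of the construct is not given in the sources used here, and reads of a construct with altered codons would be counted only in part. Of the receptor chains, IL2RB, the signalling beta chain shared with the IL15 receptor (chromosome 22, 37125838 to 37175054), rose from 210 ± 23.9 to 348 ± 1.90 TPM (log2 fold change 0.73, SE 0.08, adjusted p = 0.0012, rescaled 0.48). IL2RA, the alpha chain that gives high affinity, was at 116 ± 9.31 and 125 ± 5.43 TPM and did not pass (adjusted p = 0.330). It lies on chromosome 10 in a window whose genes were lower in mbIL2 cells as a group (below). IL2RG, the common gamma chain, passed narrowly at 0.21 (adjusted p = 0.0357) but was -0.04 after rescaling, and it lost the call when any library but vector replicate 3 was left out (adjusted p up to 0.119).

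Downstream of the receptor, JAK3, the kinase bound to the gamma chain, rose from 56.7 ± 7.98 to 106 ± 2.04 TPM (0.91, SE 0.10, adjusted p = 0.00108, rescaled 0.65). STAT5A and STAT5B, the transcription factors that IL2 activates, rose by 0.47 and 0.32 but by 0.22 and 0.07 after rescaling, where neither passed. Both lie in a chromosome 17 window whose 184 genes had a median 0.24 above that of all genes, within the permutation limit (below). JAK1 was 131 ± 21.6 and 154 ± 4.70 TPM and did not pass (adjusted p = 0.127), though it did without vector replicate 3 (0.37, adjusted p = 0.00167). PIK3CD, a catalytic subunit of PI3 kinase, rose by 0.61, while the Src-family kinase LCK fell by 0.41. Of the 22 tested genes of the IL2 receptor and JAK-STAT list, 11 rose, 3 fell and 8 did not pass. Adjusted over the list alone, 12 rose and 3 fell, and after rescaling 7 rose and 4 fell. Without vector replicate 1 or any of mbIL2 replicates 1, 2 and 3, 10 rose and 1 fell. The list was not called by camera (adjusted p = 0.322), its median of 0.25 being close to that of all genes, and it became -0.01 after rescaling. Fry called its genes as rising on balance (adjusted p = 8.4e-04).

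Known STAT5 targets went both ways. The kinase PIM1 rose from 324 ± 32.5 to 511 ± 17.1 TPM (0.66, adjusted p = 0.00162, rescaled 0.41), and SOCS2, a feedback inhibitor of cytokine signalling, was at 64.0 ± 13.2 and 41.2 ± 1.79 TPM (-0.61, adjusted p = 0.0151), a call lost without mbIL2 replicate 2 or 3 (adjusted p up to 0.0639). CISH, another feedback inhibitor, was at 160 ± 44.4 and 166 ± 7.55 TPM, and MYC at 131 ± 11.8 and 133 ± 10.6 TPM. Neither passed (adjusted p = 0.724 and 0.893). BCL2, the survival factor, was at 40.4 ± 2.68 and 35.5 ± 1.95 TPM (adjusted p = 0.103) and passed as lower after rescaling (-0.43, adjusted p = 0.0114) and without vector replicate 3 (-0.24, adjusted p = 0.0264). SOCS1 was below the filter, at 0.933 ± 0.662 and 0.327 ± 0.0896 TPM. Of 25 tested targets, 5 rose, 8 fell and 12 did not pass, with 6 and 8 adjusted over the list alone and 4 and 10 after rescaling. Without vector replicate 3 these were 7 and 12, without mbIL2 replicate 2, 5 and 5, and without mbIL2 replicate 3, 3 and 5. IL18RAP, a subunit of the IL18 receptor, fell the most among the named members, from 45.9 ± 4.65 to 9.34 ± 0.925 TPM (-2.18, adjusted p = 6.1e-05). Camera placed the list below other genes (adjusted p = 0.00917), with adjusted p = 0.656 with an estimated correlation.

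**Figure D1:**
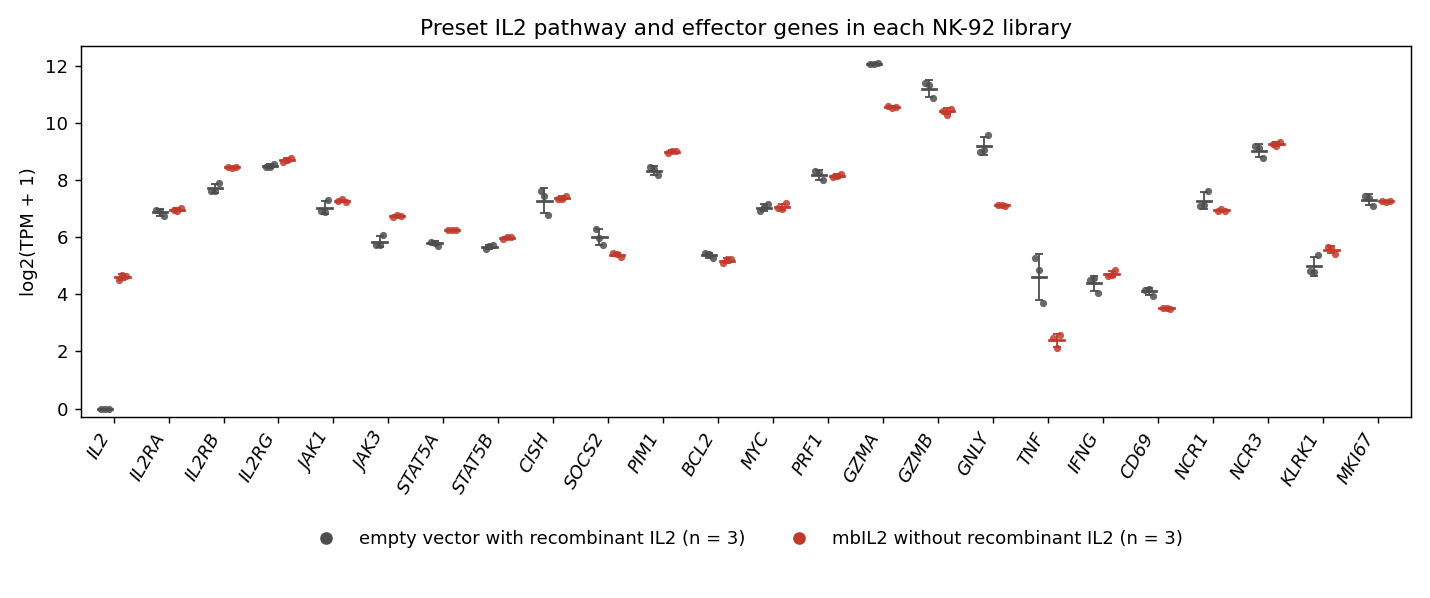
Each point is the log2(TPM + 1) of a gene fixed in advance in 1 library, grey for empty-vector cells with recombinant IL2 and red for mbIL2 cells without it, with bars for the mean ± SD of 3 libraries. IL2 is at 0 in the 3 vector libraries and IL2RB, JAK3 and PIM1 are higher in mbIL2 cells, while GZMA, GZMB, GNLY and TNF are lower.

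GZMA, the tryptase of cytotoxic granules (chromosome 5, 55102648 to 55110252), fell from 4341 ± 48.6 to 1522 ± 40.4 TPM (-1.51, SE 0.05, adjusted p = 1.4e-05). GZMB, the granzyme that activates caspases, fell from 2401 ± 450 to 1367 ± 103 TPM (-0.80, SE 0.14, adjusted p = 0.00585), and GNLY, which encodes the membrane-lytic granulysin, from 600 ± 137 to 138 ± 0.348 TPM (-2.09, SE 0.15, adjusted p = 2.2e-04). The cathepsin CTSW fell by 1.36. PRF1, which encodes the pore former perforin, was at 290 ± 32.6 and 284 ± 12.1 TPM and did not pass (adjusted p = 0.830). The death ligand TNFSF10 (TRAIL) rose from 13.6 ± 1.17 to 54.2 ± 2.98 TPM (1.92, adjusted p = 4.6e-05). Of the 25 genes of the cytotoxic granule and death ligand list, 9 rose, 8 fell and 8 did not pass, with 9 and 9 adjusted over the list alone and 4 and 13 after rescaling. Camera placed the list below other genes (adjusted p = 0.0135), with adjusted p = 0.656 with an estimated correlation, and fry called it as lower on balance (adjusted p = 0.0446).

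TYROBP (DAP12), an adaptor of activating receptors, fell from 193 ± 38.4 to 36.4 ± 2.60 TPM (-2.36, adjusted p = 1.2e-04), and HCST (DAP10), the adaptor of NKG2D and the neighbour of TYROBP on chromosome 19, from 931 ± 123 to 353 ± 5.75 TPM (-1.39, adjusted p = 2.0e-04). SLAMF7 rose from 238 ± 50.6 to 622 ± 45.4 TPM (1.40, adjusted p = 8.4e-04) and the Fc receptor FCGR3A from 2.07 ± 0.621 to 6.69 ± 0.683 TPM (1.34). KLRK1, which encodes NKG2D and overlaps the read-through gene KLRC4-KLRK1, passed at 0.57 (adjusted p = 0.0319) but not after rescaling (0.33, adjusted p = 0.153), nor when any library but vector replicate 3 was left out (adjusted p up to 0.105). The natural cytotoxicity receptors NCR1, at 157 ± 33.6 and 122 ± 2.76 TPM, and NCR3, at 525 ± 78.9 and 623 ± 29.7 TPM, did not pass (adjusted p = 0.0872 and 0.112). NCR1 passed as lower after rescaling (-0.60, adjusted p = 0.0131) and without vector replicate 3 (-0.18, adjusted p = 0.0139). Of 26 tested activating receptors and adaptors, 11 rose, 4 fell and 11 did not pass (camera adjusted p = 0.942). Adjusted over the list alone 13 rose and 4 fell, and after rescaling 7 and 6. Without vector replicate 3, 16 rose and 5 fell, and without vector replicate 1, 9 and 4. Of 16 tested inhibitory receptors, 6 rose and 4 fell, as they did adjusted over the list alone, and 4 rose and 6 fell after rescaling. Without mbIL2 replicate 1 or 3, 5 rose and 2 fell. Among them LAIR1 rose by 2.20, from 0.420 ± 0.287 to 5.48 ± 0.725 TPM, and CD200R1 by 1.88. KIR2DL4 and HAVCR2 fell by 0.49 and 0.55 (camera adjusted p = 0.491 for the list).

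Among cytokines, TNF fell from 25.9 ± 12.9 to 4.27 ± 0.854 TPM (-2.23, SE 0.38, adjusted p = 0.00488), with vector replicates at 37.6, 27.9 and 12.1 TPM, and the chemokines XCL2 and CCL4 fell by 1.02 and 0.88. CXCL8 rose from 0.350 ± 0.165 to 6.43 ± 0.688 TPM and IL10 from 27.1 ± 2.12 to 59.8 ± 2.70 TPM. IFNG, the main effector cytokine of natural killer cells, was at 20.1 ± 3.82 and 25.4 ± 2.10 TPM and did not pass (adjusted p = 0.105). Of 17 tested cytokines and chemokines, 3 rose, 6 fell and 8 did not pass, the same counts adjusted over the list alone, with 3 and 8 after rescaling. Of 26 chemokine receptors and adhesion molecules, 8 rose and 8 fell, also adjusted over the list alone, with 7 and 10 after rescaling. CCR7, the receptor that guides cells to lymph nodes, rose from 3.97 ± 0.556 to 28.1 ± 0.669 TPM (2.56, adjusted p = 2.9e-05), and the selectin ligand SELPLG by 0.88. CD44 fell from 332 ± 24.0 to 143 ± 6.72 TPM (-1.21), and the activation marker CD69 fell by 0.58. The median of the list of chemokine receptors and adhesion was -0.01 and its mean 0.10. Camera placed cytokines and this list below other genes (adjusted p = 0.0386 and 0.0470), with adjusted p = 0.656 with an estimated correlation for both. The camera calls were lost after rescaling (0.149 and 0.189). They were also lost without vector replicate 1 or 2 or mbIL2 replicate 2, and for the receptor list without mbIL2 replicate 3 (adjusted p up to 0.0953 and 0.0868).

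Of the NF-kB targets, 5 of 21 rose and 5 fell, as they did adjusted over the list alone, with 3 and 9 after rescaling. Without vector replicate 1, 3 rose and 5 fell, without vector replicate 3, 5 and 8, and without any of the other libraries, 3 and 4. The inhibitor gene NFKBIA fell from 181 ± 26.6 to 97.5 ± 7.73 TPM (-0.88), and CFLAR and BCL3 rose by 0.78 and 0.54. Camera placed the list below other genes (adjusted p = 0.0386), with adjusted p = 0.656 with an estimated correlation, 0.118 after rescaling and up to 0.116 without vector replicate 1 or 2 or mbIL2 replicate 2. Of 26 lymphoid transcription factors, 8 rose and 5 fell, also adjusted over the list alone, and 6 rose and 10 fell after rescaling (camera adjusted p = 0.144). IKZF2 and IRF1 rose by 0.85 and 0.76, while TOX2 fell by 0.91 and ID3, an inhibitor of E proteins, by 1.3, to 11.2 TPM. The median of this list was 0.04 and its mean -0.04.

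Interferon-stimulated genes were the only list of the 29 tested that camera placed above other genes. Of its 41 tested members, 31 rose, 4 fell and 6 did not pass, with 32 and 4 adjusted over the list alone and 26 and 5 after rescaling. The list median was 0.76, and 0.53 after rescaling (camera adjusted p = 8.2e-04), with adjusted p = 0.656 with an estimated correlation, and fry called it as higher on balance (adjusted p = 0.00237). IFI27 rose from 255 ± 23.6 to 756 ± 63.0 TPM (1.56) and XAF1 from 9.08 ± 1.64 to 47.9 ± 2.27 TPM (2.29). IFI6 fell from 291 ± 15.1 to 174 ± 6.39 TPM (-0.74) and IFIT2 from 7.22 ± 0.944 to 2.99 ± 0.249 TPM (-1.04).

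Beside IL2, the largest rises started from vector means between 0.0367 (KCTD3) and 6.21 TPM (FXYD2). PLXND1, a semaphorin receptor (chromosome 3, 129555175 to 129606818), went from 0.730 ± 0.185 to 59.0 ± 1.81 TPM (5.12, SE 0.11, adjusted p = 6.2e-06), and ALDH1L1, a folate enzyme on the same chromosome (126103562 to 126197994), from 0.470 ± 0.148 to 45.8 ± 1.89 TPM (adjusted p = 6.2e-06). KIT, the stem cell factor receptor, went from 0.0467 ± 0.0723 to 24.6 ± 1.3 TPM (4.61, adjusted p = 7.6e-06). LPAR6, FXYD2, CRYBA4, KCTD3 and CAPN8 rose by 4.44, 4.09, 4.06, 4.03 and 3.91. In the other direction, the guidance receptor ROBO1 fell from 64.0 ± 3.28 to 1.15 ± 0.247 TPM (-4.93, adjusted p = 6.2e-06), CHI3L1, a secreted chitinase-like protein, from 817 ± 309 to 34.9 ± 5.42 TPM (-4.44), and the non-coding RNA LINC00892 from 43.5 ± 9.73 to 0.190 ± 0.0200 TPM (-5.20). SCHIP1, which overlaps IQCJ-SCHIP1, ADTRP, GPR84 and ANK3 also fell (-4.22, -3.86, -3.64 and -3.40).

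Calcium-binding S100 genes of myeloid cells made up the rest of the largest falls. S100A9 (chromosome 1, 153357854 to 153361027) went from 3756 ± 1094 to 204 ± 22.7 TPM (-4.15, SE 0.23, adjusted p = 9.5e-05), with vector replicate 3 at 2492 and the other vector libraries at 4386 and 4390 TPM. S100A8 went from 170 ± 70.6 to 8.71 ± 4.27 TPM and S100A12 from 150 ± 42.3 to 3.11 ± 0.823 TPM (-4.12 and -5.18). Of the myeloid markers, 4 of 5 tested genes fell and CD33 rose from 0.197 ± 0.102 to 2.73 ± 0.892 TPM, on both scales and adjusted over the list alone (camera adjusted p = 0.00200, fry adjusted p = 0.00871, camera adjusted p = 0.656 with an estimated correlation). The other 8 markers of that list were below the filter, with CD14 and LYZ at most at 0.21 TPM and MPO listed at 0 in all 6 libraries.

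In some stretches of the chromosomes, neighbouring genes changed together. Of 134 windows of 20 Mb, 7 had a median further from that of all genes than any window in 1000 permutations (largest permuted distance 0.333), and all 7 were lower in mbIL2 cells. The highest windows lay just within that limit. They were at 0.330 on chromosome 17 from 0 to 20 Mb and 0.329 on chromosome 1 from 180 to 200 Mb. Both lay above the 0.274 that the largest distance stayed under in 95% of permutations. The limit was the same for windows of every size, and so strictest for those with many genes. It therefore does not show that only falls were regional. In the chromosome 17 window, 81.5% of 189 genes lay above the median of all genes. CCR7, TOP2A, STAT5A and STAT5B lie in another window of chromosome 17, at 0.24. On chromosome 1 from 140 to 160 Mb, which holds S100A8, S100A9, S100A12 and MCL1, the median over 190 genes was -0.85 relative to all genes, and 15.3% of genes lay above the median of all genes. On chromosome 10 it was -0.57 from 0 to 20 Mb, which holds IL2RA, VIM and ATP5F1C, and -0.77 from 20 to 40 Mb. The other windows, on chromosome 11 from 0 to 20 Mb, chromosome 8 from 20 to 40 Mb, chromosome 1 from 20 to 40 Mb and chromosome 15 from 20 to 40 Mb, had medians of -0.36, -0.35, -0.35 and -0.34. Of the named genes, LCK, ID3, IFI6, PMVK, PFKP, E2F2, TNFRSF10A and TNFRSF10B also lie in them.

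**Figure D2:**
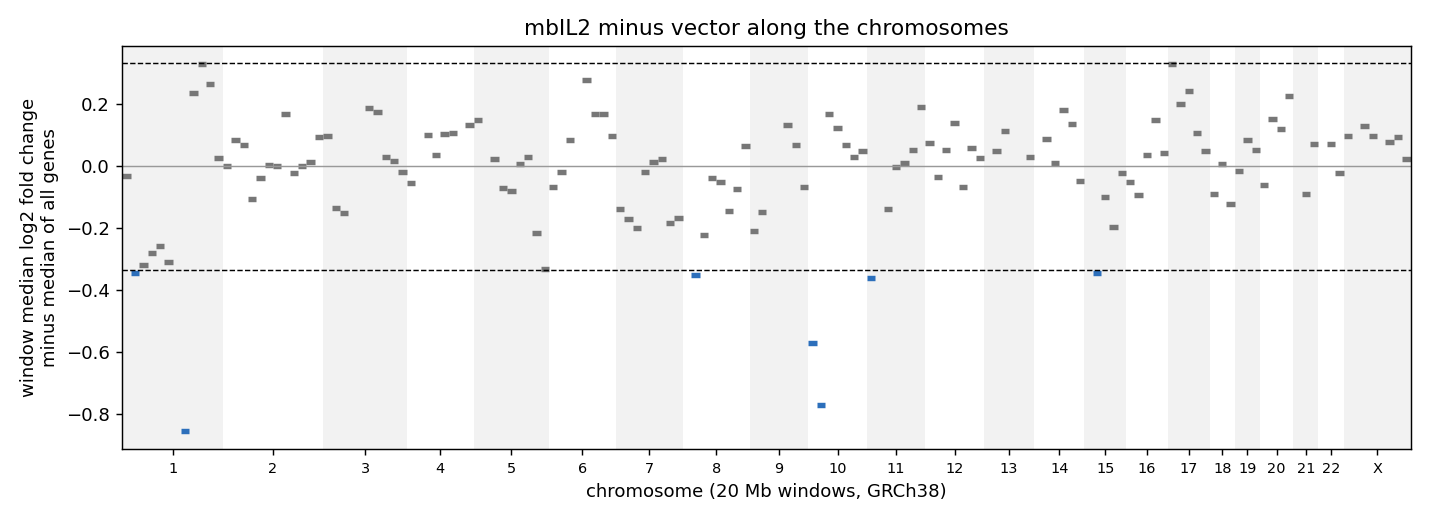
Each bar is a 20 Mb window of GRCh38 and its height the median log2 fold change (mbIL2 minus vector) of its protein-coding genes, minus the median of all such genes. Blue bars, 7 windows, lie beyond the dashed lines at 0.333 from 0, the largest distance in 1000 permutations, and the lowest is -0.85 on chromosome 1.

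Of 40 nuclear genes of oxidative phosphorylation, 9 rose, 7 fell and 24 did not pass, also adjusted over the list alone, and 0 rose and 22 fell after rescaling. Without vector replicate 3, 10 rose and 21 fell, without vector replicate 2, 8 and 4, and without mbIL2 replicate 3, 7 and 4. ATP5F1C fell from 128 ± 8.66 to 68.2 ± 1.93 TPM (-0.90) and COX6C from 772 ± 38.2 to 500 ± 2.04 TPM (-0.62). Of 47 cytosolic ribosomal proteins, 6 rose and 14 fell, also adjusted over the list alone, and 0 and 34 after rescaling, although with quantile normalization the mean of the list was 0.02 above other genes. RPL5 and RPS2 fell by 0.72 and 0.53. When vector replicate 3 was left out, 12 ribosomal proteins rose and 15 fell. Without any other library 1 rose, and 13 fell without vector replicate 1, 10 without vector replicate 2 and 9 without any of the mbIL2 replicates.

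Of 13 mitochondrially encoded genes, 1 rose and 3 fell, MT-ND6 by 0.88 and MT-ND5 by 0.39, also adjusted over the list alone, and 0 and 10 after rescaling. Without vector replicate 3, 2 rose and 5 fell, without mbIL2 replicate 1, 0 and 3, and without any of the other libraries, 0 and 2. Camera placed the lists of oxidative phosphorylation, ribosomal proteins and mitochondrially encoded genes below other genes (adjusted p = 0.00297, 3.1e-04 and 0.00275), with adjusted p = 0.798, 0.707 and 0.656 with an estimated correlation. Of 22 glycolysis genes 4 rose and 5 fell (5 and 7 adjusted over the list alone, 1 and 10 after rescaling), and PFKL rose by 0.51. Without vector replicate 3, 4 rose and 10 fell, without vector replicate 1, 4 and 1, without mbIL2 replicate 2, 3 and 1, and without any of the other libraries, 2 and 0. Of 40 MYC targets and ribosome biogenesis genes 4 rose and 4 fell (1 and 2 adjusted over the list alone, 0 and 11 after rescaling), among them WDR12, which fell by 0.64. With vector replicate 3 left out, 4 rose and 17 fell. Without vector replicate 1 these were 3 and 2, without vector replicate 2, 2 and 2, without mbIL2 replicate 1 or 3, 1 and 2, and without mbIL2 replicate 2, 1 and 3. Camera placed glycolysis and MYC targets below other genes (adjusted p = 0.0386 and 0.0135), with adjusted p = 0.829 and 0.940 with an estimated correlation, and both calls were lost without vector replicate 1 or 2 or mbIL2 replicate 2 (adjusted p up to 0.116 for each).

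Of 20 genes of oxidative stress and NRF2, 4 rose and 8 fell, 4 and 11 adjusted over the list alone and 2 and 13 after rescaling. The peroxiredoxin PRDX1 fell from 213 ± 59.3 to 65.1 ± 6.67 TPM (-1.66) and the ferritin chain FTH1 by 0.91. HMOX1, at low values, rose from 0.823 ± 0.337 to 2.65 ± 0.155 TPM (1.02). Of 22 replication-dependent histone genes, 7 fell and 0 rose, also adjusted over the list alone, and 8 and 0 after rescaling. Without mbIL2 replicate 1 or 3, 3 fell and 0 rose. Leaving out vector replicate 3, which lay above the other vector libraries on this list (median 0.48), gave 6 lower and 1 higher, and the list median went from -0.63 to -0.39. H1-2 fell by 0.57 and H2BC12 by 0.64. Camera placed the NRF2 and histone lists below other genes (adjusted p = 8.4e-04 and 4.7e-05), with adjusted p = 0.656 with an estimated correlation for each.

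Of 38 genes of G1/S and DNA replication 7 rose, 3 fell and 28 did not pass (6 and 3 adjusted over the list alone), and 0 rose and 6 fell after rescaling. When vector replicate 3 was left out, 9 rose and 10 fell. Without vector replicate 2 these were 3 and 1, and without mbIL2 replicates 1, 2 and 3 they were 1 and 3, 2 and 1, and 1 and 1. E2F1 fell from 110 ± 13.7 to 66.5 ± 1.51 TPM (-0.72). Of 40 genes of G2/M and mitosis 7 rose, 2 fell and 31 did not pass, also adjusted over the list alone, with 2 and 7 after rescaling. Leaving out vector replicate 3 gave 8 and 6. Without vector replicate 1 or 2 or mbIL2 replicate 2 these were 6 and 1, without mbIL2 replicate 1, 5 and 1, and without mbIL2 replicate 3, 4 and 1. TOP2A rose from 278 ± 14.6 to 473 ± 15.8 TPM (0.77) and CDC20 fell by 0.52. MKI67, a marker of cycling cells, was at 159 ± 20.4 and 152 ± 3.19 TPM and did not pass (adjusted p = 0.657), though it did without vector replicate 3 (-0.17, adjusted p = 0.0213). Camera called neither list (adjusted p = 0.491 and 0.942), but called that of G1/S as lower after rescaling (0.0362) and without vector replicate 3 (0.0321). With an estimated correlation both had an adjusted p of 0.976.

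Of the 29 lists tested, camera called 14, of which 1 was higher and 13 lower than other genes. Camera also called from 7 to 14 lists in splits of the libraries that mixed the groups. With an estimated correlation it called 0 (0 at an unadjusted p under 0.05, the lowest unadjusted p being 0.0609), and fry called 5 (10 at an unadjusted p under 0.05).

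**Figure D3:**
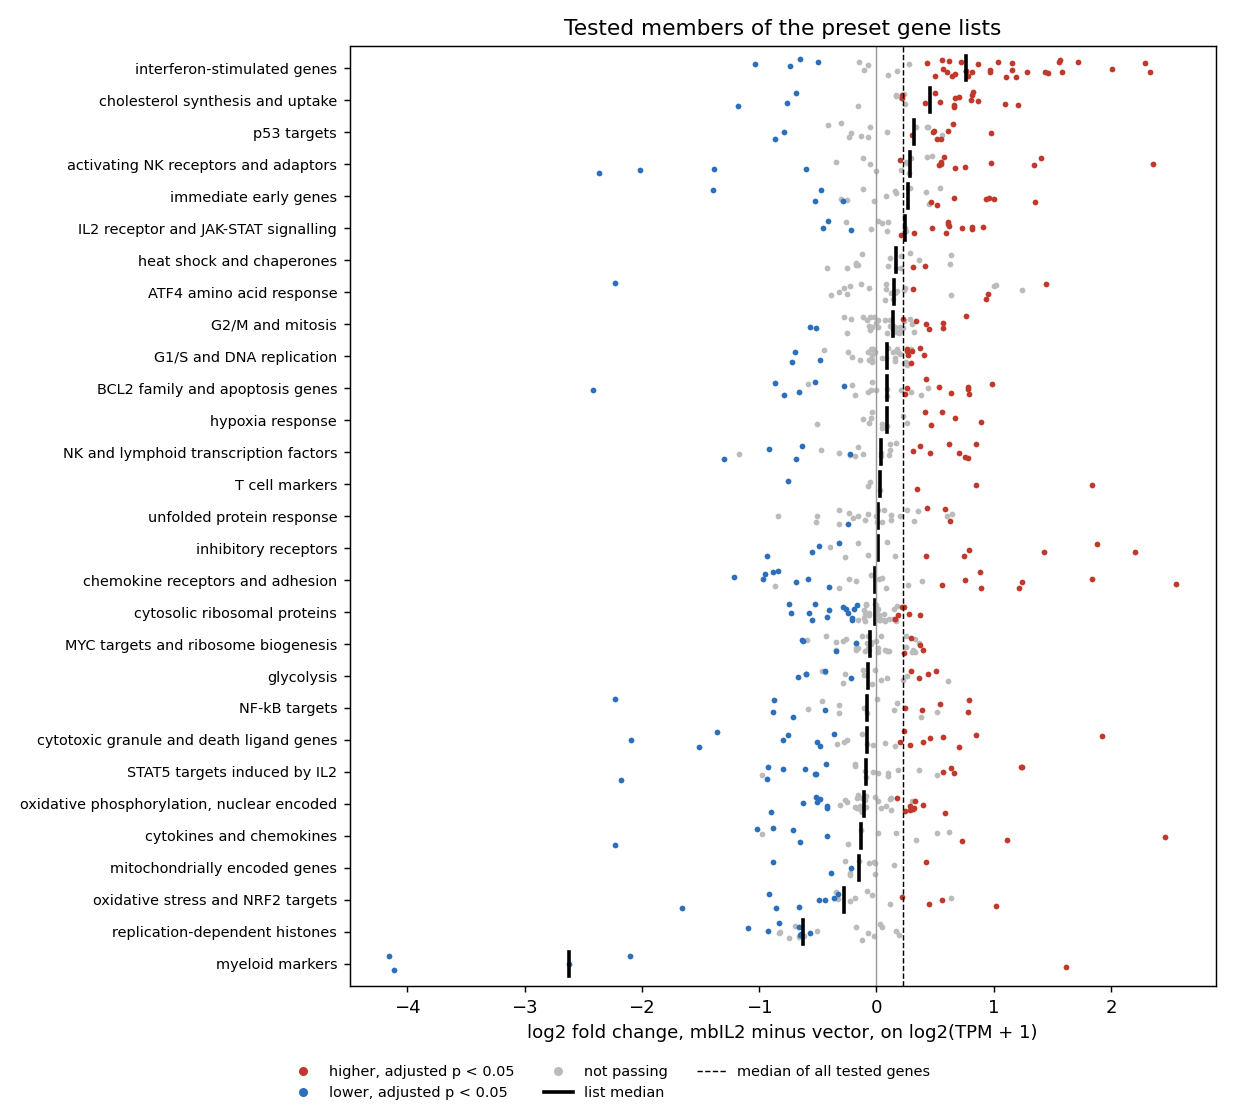
Points are the tested members of each of 29 gene lists fixed in advance, placed by log2 fold change (mbIL2 minus vector) on log2(TPM + 1), red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise. Black ticks are list medians, 0.76 for interferon-stimulated genes at the top and -2.62 for myeloid markers at the bottom, and the dashed line is the median of all tested genes, 0.23.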

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

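The split into higher and lower genes changed with scaling. With median-of-ratios rescaling, genes higher in mbIL2 numbered 1890 and genes lower in mbIL2 2487, and with quantile normalization 2345 and 2128, since both recentre the libraries whose median moved by 0.23. Requiring an absolute log2 fold change of at least 1 left 617 and 269 by construction. Leaving out each library in turn gave 2953 to 5535 higher genes, 915 to 1906 lower genes and 10 to 15 lists, the most higher and lower genes without vector replicate 3. Camera called 3 lists with quantile normalization and 0 with an estimated correlation, and fry called 5. A value counted as reversed where it changed sign and passed in either fit. These values were those of IL2RG (-0.0414), CAD (-0.0168) and RPS12 (-0.0186) with median-of-ratios rescaling. With quantile normalization it was that of the cytosolic ribosomal proteins (0.0197 above other genes). The first 3 follow from the recentring, since their log2 fold changes of 0.21, 0.23 and 0.23 were close to the median shift of 0.23 that it removes, and for the ribosomal proteins the cause was not tested. In pseudocounts, filters, limma without trend and limma with robust estimation, the numbers of higher and lower genes stayed within 1.5 times the reported ones, as did the number of called lists with the pseudocounts and filters. Lists were not tested again without trend or with robust estimation. Counts within lists moved further in some: ribosomal proteins went from 6 higher and 14 lower to 1 and 8 with no filter on low values and to 2 and 10 without trend, and glycolysis genes from 4 and 5 to 4 and 0 with no filter. The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at 0.00448, -0.0327 and -0.0852, and 0 of 6 libraries were closest to their own number. With the replicate block 3456 genes were higher, 1019 lower and 14 lists called, and 4386 of 5871 calls were kept in the same direction. Chosen after seeing the data, the fit without the genes of the 7 shifted windows gave 4465 higher, 1030 lower and 14 lists, not the same 14: cholesterol and the unfolded protein response were gained, glycolysis was lost, and the myeloid markers, with 3 members left, could not be tested. Over all settings 2157 values of named genes counted as unchanged, 113 were weaker, 8 stronger and 3 reversed, and for lists these were 391, 60, 10 and 1. A change of sign counted as unchanged where neither value passed, as for IL2RA, CISH and MYC after rescaling (-0.15, -0.16 and -0.24). Read depth is unknown, so what it limits was not assessed.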

Other observations

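Genes of cholesterol synthesis and uptake moved mostly up in mbIL2 cells: 15 of 24 tested members rose, 3 fell and 6 did not pass, also adjusted over the list alone, and 10 rose and 3 fell after rescaling. LSS, which closes the sterol rings, rose from 28.1 ± 1.65 to 50.3 ± 2.41 TPM (0.82) and MVD, of the mevalonate pathway, from 62.7 ± 2.90 to 100.4 ± 3.76 TPM (0.67). PMVK fell by 1.18 and lies in the shifted window of chromosome 1. The list was not called by camera (adjusted p = 0.144, and adjusted p = 0.940 with an estimated correlation). At the preset correlation it was called without the genes of the shifted windows (0.0252). Of 15 tested hypoxia genes 5 rose, MXI1 by 0.89 and KDM3A by 0.56, and 0 fell, also adjusted over the list alone. Without vector replicate 1, 3 rose and 1 fell, and without vector replicate 2 or mbIL2 replicate 1 or 3, 3 and 0. After rescaling 2 rose and 3 fell, so fry's call of a balance upwards (adjusted p = 0.00871) sits beside a camera adjusted p of 0.942 and a list median of 0.09 that becomes -0.15 on that scale. Of 22 p53 targets 8 rose and 2 fell, also adjusted over the list alone, and 3 and 5 after rescaling (camera adjusted p = 0.788), with MDM2 rising by 0.61. Without vector replicate 3 these were 10 and 5, and without vector replicate 2 or mbIL2 replicate 2 or 3 they were 4 and 2. Of 28 BCL2 family and apoptosis genes 9 rose and 6 fell, also adjusted over the list alone, and 5 and 9 after rescaling (camera adjusted p = 0.292). The death receptor TNFRSF10A fell by 2.42, from 6.43 ± 2.29 to 0.353 ± 0.144 TPM, and the death receptor FAS by 0.86. TNFRSF10A lies in the shifted window of chromosome 8.

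DDIT4, an mTOR inhibitor in the ATF4 amino acid response list, rose from 198 ± 43.5 to 535 ± 29.4 TPM (1.45), and the transcription factor CEBPB of the same list fell from 87.2 ± 27.6 to 17.1 ± 1.04 TPM (-2.23). In that list 4 of 26 tested genes rose and 1 fell, 2 and 1 adjusted over the list alone and 2 and 3 after rescaling (camera adjusted p = 0.562), and without vector replicate 3 it was 12 and 1. Without vector replicate 1 or 2 or mbIL2 replicate 2 or 3 it was 2 and 1. In the unfolded protein response list 3 of 27 rose and 1 fell, also adjusted over the list alone, and 2 and 5 after rescaling (camera adjusted p = 0.0826). Without vector replicate 3, 10 rose and 1 fell, without vector replicate 2 or mbIL2 replicate 3, 3 and 0, and without mbIL2 replicate 2, 3 and 2. With the preset correlation, without vector replicate 1 or 2 or mbIL2 replicate 2 camera called the list as lower (lowest adjusted p 0.0133), as it did without the genes of the shifted windows, beside adjusted p = 0.940 with an estimated correlation. Of 17 heat shock and chaperone genes 2 rose, with 0 adjusted over the list alone and 0 after rescaling (camera adjusted p = 0.619). Without vector replicate 3, 4 rose and 6 fell, without mbIL2 replicate 2, 1 and 0, and without vector replicate 2 or mbIL2 replicate 1 or 3, 0 and 0. Of 23 immediate early genes 7 rose and 4 fell, 8 and 4 adjusted over the list alone and 3 and 4 after rescaling (camera adjusted p = 0.895). At low values, NR4A1 rose from 0.927 ± 0.193 to 3.92 ± 0.537 TPM (1.35) and its relative NR4A2 fell from 6.55 ± 1.45 to 1.85 ± 0.215 TPM (-1.39). Of the T cell markers 3 of 7 tested rose and 1 fell, also adjusted over the list alone, and 2 and 3 after rescaling, with CD6 rising by 1.84 and CD28 falling from 29.3 ± 4.23 to 16.9 ± 1.17 TPM, while 6 others, CD3D and CD8A among them, stayed at or under 0.11 TPM in every library (camera adjusted p = 0.942). The B cell list had 1 tested gene, PAX5, which rose from 7.24 ± 0.994 to 27.4 ± 0.980 TPM, and the list of epithelial and kidney line markers had 2, of which VIM fell by 0.84 and LIN28B, at 8.44 ± 0.973 and 11.4 ± 1.13 TPM, passed as higher (adjusted p = 0.0367) but not after rescaling (0.16, adjusted p = 0.377) nor when any of the 6 libraries was left out (adjusted p up to 0.131). Both were too small for a list test.

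In what follows, the tests chosen only after the result was seen are those of the S100 cluster and of GC content in the windows, and those of admixture, of IL2 signal and of stress in vector replicate 3. The libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the only 1 of the 10 with as many genes, 4533 higher and 1338 lower, where the highest count in any other split was 4 in either direction. In a mixed split the difference between the groups enters the spread within each side, so few genes can pass. Those low counts follow from the design and do not gauge the real count. Mixed splits also keep part of the group difference, so their list calls are not free of it. For gene lists, 2 of the 10 splits reached the 14 lists called, so that the preset camera calls were matched by another split. Every split that mixed the groups gave from 7 to 14 lists. The number of preset camera calls therefore does not set the real grouping apart from mixed ones.

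Neighbouring genes moved together in blocks: the farthest window lay -0.855 from all genes against a largest permuted distance of 0.333. Measured against the vector libraries, the 3 mbIL2 libraries lay at -0.84, -0.80 and -0.86 and the 3 vector libraries between -0.01 and 0.01. This reference centres the vector libraries near 0, so their values show only their spread. Regulation of the S100 cluster alone is argued against, since 124 of the 190 genes of that window passed as lower. Its median was -0.841 without 10 genes of the S100, SPRR, LCE, FLG and IVL families, but so few genes could move it only a little. GC content as the whole cause is argued against too, since the window median was -0.842 after the trend on GC content was removed. A difference in copy number between the cell populations cannot be told apart from other regional causes, since any of these would give such a window, and no DNA was analysed here. In 5 Mb steps on chromosome 1 the shift was even from 20 to 120 Mb, between -0.38 and -0.20 in each step with at least 10 genes, and uneven further on, at -0.21 from 145 to 150 Mb, -0.90 and -0.98 in the next steps and 0.24 from 160 to 165 Mb. An effect of the IL2 form on whole regions also stays open, as untested.

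The median gene was 0.23 higher in mbIL2 cells. The explanation that a few abundant genes that fell left room for the rest is argued against as the main cause, since the median was 0.20 without the 50 most abundant genes. Transcript length and GC content are argued against as the main cause, since the shift was present across the range of both. In each 25% of genes, by length or by GC content, the median was between 0.19 and 0.27. A smaller part for either cannot be told apart from other causes. The 25% of genes highest in each differed from the 25% lowest by 0.0710 for length and by -0.0731 for GC content. A change in the total RNA of the cells or in the breadth of transcription, through the IL2 form or otherwise, stays open and could not be measured, as TPM holds no absolute scale.

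Vector replicate 3 stood apart from vector replicates 1 and 2. Admixture of mbIL2 cells is argued against, since over the 10 genes of largest rise the median gap of vector replicate 3 was -0.327% of the gap of mbIL2 cells, and length bias likewise, with 0.00504 between the longest and the shortest 25% of genes. A weaker IL2 signal in that culture may contribute, as the STAT5 targets deviated by -0.25 (median), at percentile 0.11 of 10000 random lists matched on mean expression, but the value is not particular to IL2, since myeloid markers (-0.82), glycolysis and heat shock (-0.40 each), MYC targets (-0.39), cholesterol (-0.34), NF-kB targets (-0.33), cytokines and G1/S (-0.32 each) deviated further. Amino acid or endoplasmic reticulum stress may contribute as well, since the ATF4 list deviated by 0.80 and the unfolded protein response list by 0.64, each at percentile 100 of such lists. Lists not tied to stress also deviated upwards, among them histones (0.48), activating receptors (0.40), T cell markers (0.38) and inhibitory receptors (0.33). A weaker IL2 signal and stress are both hypotheses from 1 library, and neither separates cause from consequence.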
